A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

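Poly(A) RNA was measured by sequencing in 5 strains of the budding yeast Saccharomyces cerevisiae, taken from asynchronous cultures in exponential growth on rich medium. By the labels, the strains were the parent BY4741 (WT, mating type a) and 4 mutants that each lack 1 gene of the INO80 chromatin remodelling complex: ino80d, arp8d, arp5d and ies6d. In each mutant the LEU2 marker gene stands in place of the deleted gene. The libraries were made with the TruSeq RNA v2 kit, which does not record the strand of origin, and were sequenced on an Illumina HiSeq instrument. Values of genes that overlap another gene are therefore uncertain.

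The deposited values are FPKM (fragments per kilobase, scaled to the number of mapped fragments) for each open reading frame (ORF) or other feature, computed by the authors. Per the submitters' processing notes, the tools were TopHat2 and Cuffdiff on genome build sacCer3. Their versions, the annotation and the library size setting are not stated. Each strain has 1 value, which stands for 2 biological replicates, so that there is no replicate error, no test of a mutant against WT and no paired analysis. A test of arp5d with ies6d against arp8d with ino80d, which would treat different mutants as replicates, was left out, as planned for a table with 1 value per strain. Counts of fragments are not given and the depth of each library is unknown, so neither counting intervals nor detection limits were computed.

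All 5 columns of the table were used and none was left out. Of 6567 features, 5888 carried an ID equal to a locus tag of the R64 annotation, which has the same assembly as sacCer3, and 679 did not. Symbols, positions and coding length come from that annotation. Near-identical copies were searched with blastn 2.17.0 at 90% identity over at least 50% of the length. Where 1 exists, the value of the gene is uncertain, because it is not known how reads shared by copies were assigned.

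The measure was the log2 ratio of FPKM + 1 of each mutant to WT. Features were kept when their mean over the 5 strains was at least 5 FPKM, which left 6192. Values were not rescaled between strains. Without replicates, genes were described by size alone: at least 2-fold higher or lower, and at least 1.5-fold for members of gene lists. Each mutant was compared with WT, the mutants were compared with each other by the SD of the log2 ratio over features, and arp5d with ies6d were set against arp8d with ino80d. For this last comparison a gene had to be at least 2-fold apart in each of the 4 cross pairs. Sharing between mutants was set against the overlap of independent lists and against 100 simulations of unchanged strains that share 1 WT value. The noise of these simulations was drawn from the differences between arp5d and ies6d, within bins of expression.

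For each gene list with at least 3 kept members the median log2 ratio was placed among the medians of 10000 random lists of kept features, drawn from 20 bins of mean expression with the bin composition of the list. The place is given as a percentile: 0 means below every random list and 100 above every one. Random lists matched on length as well, and random lists drawn without ribosomal protein genes, were added after the data were seen. A percentile describes how far a list stands from like features and is not a p-value.

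Named genes were chosen by a rule: the 10 highest and 10 lowest of each mutant against WT, the 10 higher and 10 lower in all 4 mutants ranked by the smallest change, the 10 highest and 10 lowest of arp5d and ies6d over arp8d and ino80d, and up to 4 members of each list with the largest mean change. The deleted genes, the marker genes, INO1, PHO5, PHO84 and the neighbours of the deleted genes were named in any case. Most genes at the top of these ranks were short features listed at 0 in 1 strain or more. The same ranks among annotated ORFs of at least 300 bp above 0 in all 5 strains (5419 features, called long ORFs here) were therefore added after the data were seen. No kept annotated ORF of at least 300 bp was listed at 0, so the second condition removed none.

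The groups, comparisons, thresholds, gene lists, named-gene rule and the alternatives on pseudocount, low-value filter, scaling, fold threshold and distance measure were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter at 20 FPKM, centring each strain on its median log2 ratio, a 1.5-fold threshold, and the median absolute log2 ratio as distance. Alternatives on features (above 0 in all strains, long ORFs) and on chromosomes (without I, III and XI) were added later. The steps were tested on simulated data, with noise in each strain of about the SD between arp5d and ies6d over long ORFs, 0.248. Over all kept features that SD was 0.536 and the spread per strain 0.379, so noise there was larger than simulated. The percentages that follow hold for the simulated noise only. Of genes simulated with a true change of 2.5-fold, 82% passed 2-fold, as did 100% at 4-fold, 16% at 1.5-fold and 0.467% of unchanged genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used. URA3 and the genes encoded by the mitochondrial genome are not analysed here.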

Results

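RNA levels of 6567 ORFs and other features were measured in 5 yeast strains: BY4741 (WT) and 4 mutants that each lacked 1 subunit gene of INO80, a complex that moves and edits nucleosomes. INO80 itself encodes the motor subunit, ARP5 and ARP8 encode actin-related proteins, and IES6 encodes a small subunit. Each strain had 1 FPKM value per feature for 2 biological replicates, so that no value below has a replicate error and no difference was tested against replicate spread. The FPKM values summed to 3381540 in WT, 3032393 in ino80d, 2774103 in arp8d, 3244579 in arp5d and 3711718 in ies6d. The median feature lay at 53.4, 54.7, 54.6, 53.6 and 53.9 FPKM in the same order. The 10 highest features held 24.6% of the sum in WT, 36.5% in ino80d, 24.9% in arp8d, 33.6% in arp5d and 35.6% in ies6d. The depth of the libraries is unknown. Positions are on R64, and rows of 4 values are given in the order ino80d, arp8d, arp5d and ies6d unless the strains are named.

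Each deleted gene was close to 0 in its own strain and expressed in the other 4. INO80 (YGL150C, chromosome VII, 221104 to 225573) lay at 25.7 FPKM in WT, 0.0257 in ino80d, 35.5 in arp8d, 34.1 in arp5d and 31.7 in ies6d. ARP8 (YOR141C, chromosome XV, 589942 to 592587) lay at 42.1 FPKM in WT, 35.5 in ino80d, 0.0986 in arp8d, 33.4 in arp5d and 29.9 in ies6d. ARP5 (YNL059C, chromosome XIV, 512668 to 514935) lay at 63.9 FPKM in WT, 61.6 in ino80d, 62.0 in arp8d, 0.0687 in arp5d and 58.1 in ies6d. IES6 (YEL044W, chromosome V, 69757 to 70257) lay at 238 FPKM in WT, 188 in ino80d, 177 in arp8d, 202 in arp5d and 0.211 in ies6d. Over the 15 genes of INO80 subunits the median log2 ratio to WT was -0.14, 0.00, -0.02 and 0.03. In each mutant 2 of the 15 genes were at least 1.5-fold higher, and the deleted gene was the only 1 at least 1.5-fold lower.

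Among the marker genes, LEU2 (YCL018W, chromosome III, 91324 to 92418), which stands in place of each deleted gene, lay at 0.0619 FPKM in WT and at 91.3, 125, 113 and 81.3 FPKM in the mutants. HIS3 (YOR202W), of which the his3 allele of BY4741 leaves a part, lay between 178 FPKM in arp8d and 238 FPKM in ino80d, with 211 in WT. MET17 (YLR303W, chromosome XII, 732542 to 733876), a gene of methionine synthesis deleted in BY4741 under its older name MET15, lay at 0.482 FPKM in WT, 0.2005 in arp5d and 0.571 in ies6d, but at 807 in ino80d and 564 in arp8d. It overlaps YLR302C. LYS2 (YBR115C, chromosome II, 469748 to 473926), a gene of lysine synthesis that the labels do not list as mutated, lay at 36.9 FPKM in WT, 32.3 in arp8d and 25.01 in ies6d, but at 0.0138 in ino80d and 0.0390 in arp5d. The strains therefore differed at MET17 and LYS2 as well as at the deleted genes. The list of marker genes held HIS3, LEU2, MET17 and URA3, but not LYS2. Of these 4 genes, 3 were measured, all but URA3, with a median log2 ratio to WT of 6.44, 6.89, -0.02 and 0.08.

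**Figure D1:**
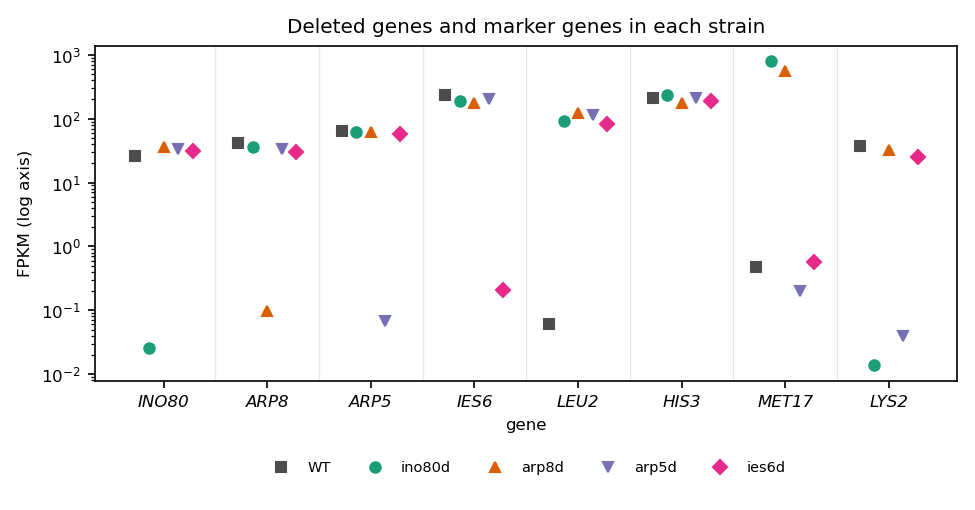
FPKM on a log axis of the 4 deleted genes and of the marker genes LEU2, HIS3, MET17 and LYS2 in each of the 5 strains, 1 point per strain. Each deleted gene lay at or below 0.211 FPKM in its own strain, LEU2 at 0.0619 FPKM in WT alone, MET17 below 1 FPKM in WT, arp5d and ies6d, and LYS2 below 1 FPKM in ino80d and arp5d.

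Genes next to the deleted ones moved little, with the exceptions YGL149W and YEL045C. YGL149W (chromosome VII, 225572 to 225877), which overlaps the start of INO80 by a few bases, lay at 15.9 FPKM in WT, 79.9 in ino80d, 5.28 in arp8d, 7.75 in arp5d and 1.46 in ies6d. YEL045C, next to IES6, lay at 0.899 FPKM in WT and at 5.82, 2.27, 5.06 and 5.17 FPKM in the mutants, and its ID was not in the annotation. In the strain that lost the gene beside them, the log2 ratio to WT was -0.30 for NUT1 in ino80d, -0.43 for SFL1 and 0.29 for LSC1 in arp8d, 0.25 for YNL058C and -0.01 for NOP2 in arp5d, and -0.45 for GTA1 in ies6d.

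The comparison of ino80d with WT asks what cells express without the motor subunit. Genes of the general stress response and of respiration were higher, and genes of phosphate uptake, purine synthesis and ribosomal proteins were lower. Of 6192 features, 422 were at least 2-fold higher and 272 at least 2-fold lower, together 11.2%. After MET17 and LEU2, the highest long ORFs were HSP30 (YCR021C), a membrane heat shock protein, at 29.8 FPKM in WT and 1009 in ino80d, HSP12 (YFL014W), a small stress protein of the plasma membrane, at 93.1 and 2584 FPKM, and YRO2 (YBR054W) at 28.9 and 710 FPKM. The lowest after LYS2 were PHO12 (YHR215W), an acid phosphatase with the near-identical copy PHO11, at 62.7 FPKM in WT and 1.12 in ino80d, then INO80 itself, TIR1 (YER011W), a cell wall mannoprotein, at 240 and 9.78 FPKM, and PHO84 (YML123C), the high-affinity phosphate transporter, at 897 and 46.4 FPKM. IMD2 (YHR216W), an IMP dehydrogenase of GTP synthesis, came next at 148 and 7.77 FPKM. Of the features 2-fold higher, 20 were among the 84 genes of chromosome I, all but 1 of which lay above the mean of the other 3 mutants. Of the 10 highest features, 9 were short or unmatched features listed at 0 in 1 strain or more, such as snR69, at 0 in WT and 3056 FPKM in ino80d.

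The comparison of arp8d with WT had the smallest number of changed features of the 4. Stress genes were higher and genes of phosphate uptake, purine synthesis and branched-chain amino acid synthesis were lower, while CHA1 was low in this strain alone. Of 6192 features, 316 were at least 2-fold higher and 152 at least 2-fold lower, together 7.56%. CHA1 (YCL064C, chromosome III, 15798 to 16880), the enzyme that breaks down serine and threonine, lay at 569 FPKM in WT and 10.4 in arp8d, against 375 in ino80d, 410 in arp5d and 510 in ies6d. After ARP8, SPL2 (YHR136C), a phosphate-regulated gene, lay at 147 FPKM in WT and 9.23 in arp8d. After MET17 and LEU2, the highest long ORFs were HSP12 at 93.1 FPKM in WT and 3040 in arp8d, HSP30 at 29.8 and 989 FPKM, and FMP48 (YGR052W), a putative protein kinase gene, at 5.54 and 126 FPKM. Of the 10 highest features, 8 were listed at 0 in 1 strain or more.

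The comparison of arp5d with WT asks what cells express without this actin-related subunit. Stress and respiration genes were higher, and phosphate, purine and branched-chain amino acid genes were lower. Of 6192 features, 399 were at least 2-fold higher and 223 at least 2-fold lower, together 10.045%. After LEU2, the highest long ORFs were HSP30 at 29.8 FPKM in WT and 1582 in arp5d, YRO2 at 28.9 and 669 FPKM, TDA6 (YPR157W) at 9.23 and 217 FPKM, and TPO2 (YGR138C), a polyamine exporter with the near-identical copy TPO3, at 17.5 and 365 FPKM. The lowest after ARP5 were IMD2 at 148 FPKM in WT and 2.94 in arp5d, LYS2, PHO12 at 62.7 and 2.23 FPKM, TIR1 at 240 and 12.2 FPKM, and PHO84 at 897 and 70.9 FPKM. All 10 of the highest features were listed at 0 in 1 strain or more.

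The comparison of ies6d with WT asks what cells express without the small subunit Ies6. Of the 4 mutants it had the highest medians for general stress and respiration genes, though not for heat shock chaperones, and phosphate and purine genes were lower. Of 6192 features, 451 were at least 2-fold higher and 220 at least 2-fold lower, together 10.8%. After LEU2, the highest long ORFs were HSP30 at 29.8 FPKM in WT and 2117 in ies6d, HSP12 at 93.1 and 3477 FPKM, YRO2 at 28.9 and 905 FPKM, and CYC7 (YEL039C), the second cytochrome c, at 5.85 and 189 FPKM. The lowest after IES6 were TIR1 at 240 FPKM in WT and 10.8 in ies6d, PHO84 at 897 and 48.3 FPKM, and PHO12 at 62.7 and 3.04 FPKM. Short genes lay higher in this strain. The median log2 ratio was 0.33 over 212 genes of up to 300 bp and -0.14 over the 790 genes of the second longest class of length. HSP30 lies on chromosome III, whose 156 genes had a median log2 ratio of 0.36 in ies6d.

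The mutants shared more changes than did simulated unchanged strains with 1 WT value and the same noise in every strain. That noise had the size seen between arp5d and ies6d, and larger noise in WT alone was not simulated. In all 4, 231 features were at least 2-fold higher and 96 at least 2-fold lower, out of 588 higher and 377 lower in any mutant. Such unchanged strains gave 17.5 higher and 18.1 lower in simulations. Among the 5419 long ORFs the counts were 170 higher and 75 lower, against 2.34 and 2.47 simulated. Across long ORFs, which are not independent replicates, the log2 ratios of pairs of mutants had a Pearson r of 0.868 to 0.931, against about 0.50 simulated from the shared WT value. Equal noise in every strain fixes this simulated value. Because the same WT value enters each comparison, an unusual WT value would move a gene in all 4 mutants alike. Features that were at least 2-fold higher in 1 mutant and lower in another numbered 11, of which 1 was a long ORF.

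The long ORFs highest in all 4 mutants, ranked by the smallest of the 4 changes, were LEU2, HSP30, YRO2, HSP12 and TDA6, with log2 ratios of HSP30 between 5.01 and 6.10. They were followed by ETR1 (YBR026C), an enzyme of mitochondrial fatty acid synthesis, at 10.4 FPKM in WT and 142 to 178 in the mutants, CYC7, HMX1 (YLR205C), the heme oxygenase, at 12.8 FPKM in WT and 170 to 216 in the mutants, and TPO2. RTC3 (YHR087W), HXT7 (YDR342C), a hexose transporter with the near-identical copy HXT6, and MF(ALPHA)1 (YPL187W) came next. The 10 highest features of all kinds also held snR69, YER053C-A, YBL107W-A, YDR371C-A and YBR200W-A, all listed at 0 in WT. Values of features listed as small nucleolar RNAs were higher as well, with medians of 0.83, 0.51, 1.03 and 0.73 in these poly(A) libraries.

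Lower in all 4 mutants were SPL2, PHO12, TIR1, PHO84, the small nucleolar RNA snR190, LEU1, HUG1, OAC1, PHO89 and RRT15, in rank order. LEU1 (YGL009C), an enzyme of leucine synthesis, lay at 472 FPKM in WT and at 64.8, 67.8, 72.0 and 70.3 FPKM in the mutants. OAC1 (YKL120W), the mitochondrial carrier of oxaloacetate and a leucine precursor, lay at 385 FPKM in WT and 61.4 to 66.3 in the mutants. HUG1 (YML058W-A), an inhibitor of ribonucleotide reductase, lay at 983 FPKM in WT and at 76.2, 164, 134 and 99.9 FPKM in the mutants. RRT15 (YLR162W-A) lies within the ribosomal DNA and was listed at 0 in ino80d and arp8d. Further down among long ORFs came ADE17, PHO5, ADE13 and MAE1 (YKL029C), the malic enzyme, at 325 FPKM in WT and 56.5 to 85.7 in the mutants.

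Genes of the phosphate (PHO) regulon, which cells turn on when phosphate is scarce, had the lowest medians of the lists in arp8d, arp5d and ies6d, and the second lowest in ino80d. Of 15 kept members, 12 were at least 1.5-fold lower in ino80d, 11 in arp8d, 12 in arp5d and 12 in ies6d, and 1, 1, 2 and 2 were at least 1.5-fold higher. The median log2 ratio was -1.83, -1.45, -1.64 and -1.84, at percentile 0 in each mutant. PHO84 lay at 897 FPKM in WT and at 46.4, 130, 70.9 and 48.3 FPKM in the mutants. PHO5 (YBR093C, chromosome II, 429548 to 430951), the main secreted acid phosphatase, lay at 147 FPKM in WT and 29.4 to 32.3 in the mutants. SPL2 lay at 147 FPKM in WT and 9.23 to 11.2 in the mutants, and PHO89 (YBR296C), a sodium-coupled phosphate transporter, at 28.9 and 2.49 to 4.40. PHM8 (YER037W), a nucleotide phosphatase gene of the same list, went the other way, from 30.4 FPKM in WT to 105 to 140 in the mutants, as did GIT1 (YCR098C), from 5.85 FPKM to 8.44, 8.89, 12.9 and 11.4.

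Genes of purine and one-carbon synthesis were lower by about 2-fold. Of 16 members, 13 were at least 1.5-fold lower in ino80d, 13 in arp8d, 12 in arp5d and 13 in ies6d, with median log2 ratios of -1.07, -1.16, -0.99 and -1.15 and percentile 0 in each mutant. ADE13 (YLR359W) lay at 1342 FPKM in WT and 244 to 336 in the mutants, ADE17 (YMR120C) at 939 and 160 to 198, and ADE2 (YOR128C) at 240 and 74.8 to 90.7. GCV3 (YAL044C), the H protein of the glycine cleavage system, was the exception, at 91.5 FPKM in WT and at 662, 631, 486 and 662 FPKM in the mutants. It lies on chromosome I.

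Genes of leucine, isoleucine and valine synthesis and transport were lower as well, in strains that all express LEU2 while WT does not. Of 12 members, 7 were at least 1.5-fold lower in ino80d and 8 in each of the other 3 mutants, and none was 1.5-fold higher. The median log2 ratio was -0.88, -0.99, -0.99 and -0.96, at percentile 0 in each. BAT1 (YHR208W), the mitochondrial branched-chain aminotransferase, lay at 1254 FPKM in WT and 287 to 335 in the mutants, and LEU9 (YOR108W) at 175 and 43.1 to 76.9. Whether this follows the LEU2 marker or the missing subunit cannot be told apart here, since every mutant has both.

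Other amino acid genes (arginine, histidine, lysine and aromatic, with HOM2 and HOM3 of the threonine and methionine branch) were lower to a smaller degree. Of 25 members, 11, 9, 11 and 8 were at least 1.5-fold lower and none higher, with medians of -0.36, -0.45, -0.32 and -0.41 and percentiles of 0.070, 0, 0.16 and 0.010. LYS2 is among those lower in ino80d and arp5d, and HOM2 (YDR158W) among those lower in ino80d, arp8d and arp5d. HIS4 (YCL030C) lay at 213 FPKM in WT and 72.5 to 83.0 in the mutants. LYS9 (YNR050C) and LYS20 (YDL182W, near-identical copy LYS21) were lowest in ino80d and arp5d. LYS9 lay at 216 FPKM in WT, 36.8 in ino80d and 40.1 in arp5d, against 125 in arp8d and 70.3 in ies6d, and LYS20 at 264, 69.6 and 116 against 180 and 170. LYS21 lay at 163 FPKM in WT and 152 to 168 in the mutants, and LYS4 at 96.8 and 75.6 to 93.8. Genes of methionine and sulfate assimilation moved less. Of 24, 5, 0, 7 and 1 were at least 1.5-fold higher and 2, 0, 0 and 0 lower, with medians of 0.25, 0.07, 0.23 and 0.08, the last of which was -0.04 without genes of chromosomes I, III and XI, although MET17 differed widely between the strains.

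The general stress genes, with those of trehalose and glycogen, had the highest medians of the lists other than the marker genes. Of 29 members, 26 were at least 1.5-fold higher in ino80d and 27 in each of the other 3 mutants, 25 of them in all 4, and none was 1.5-fold lower. The median log2 ratio was 1.35, 1.97, 1.71 and 2.55, at percentile 100 in each mutant. HSP12 lay at 93.1 FPKM in WT and 1638 to 3477 in the mutants. SOL4 (YGR248W), of the pentose phosphate pathway, lay at 3.94 FPKM in WT and at 31.7, 64.6, 60.5 and 90.9 FPKM in the mutants, and SPI1 (YER150W), a cell wall protein, at 46.4 in WT and 235 to 852 in the mutants. DDR2 (YOL052C-A), a stress gene, lay at 99.1 FPKM in WT and 1004 to 1908 in the mutants.

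Heat shock chaperones were higher in part. Of 22 members, 8 were at least 1.5-fold higher in ino80d and 5 in each of the other 3 mutants, 5 of them in all 4, and 1, 0, 1 and 2 were lower. The median log2 ratio was 0.47, 0.21, 0.27 and 0.33, at percentiles of 99.8 to 100. Without genes of chromosomes I, III and XI it was 0.10 in arp8d and 0.14 in arp5d. HSP104 (YLL026W), the disaggregase, lay at 64.9 FPKM in WT and 235 to 345 in the mutants, SSA4 (YER103W) at 23.7 and 96.0 to 135, and HSP42 (YDR171W) at 39.0 and 88.3 to 232. Proteasome genes stayed near WT. None of 32 was 1.5-fold away in any mutant, with medians of -0.06, -0.03, 0.03 and -0.01.

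Nuclear genes of the respiratory chain and ATP synthase were higher. Of 34, at least 1.5-fold higher were 23 in ino80d, 11 in arp8d, 18 in arp5d and 29 in ies6d, and none was lower. The medians were 0.76, 0.40, 0.64 and 0.90, at percentile 100 in each mutant. CYC7 lay at 5.85 FPKM in WT and at 84.0, 103, 83.9 and 189 FPKM in the mutants, NDE1 (YMR145C), an external NADH dehydrogenase, at 150 in WT and 334 to 465, and QCR9 (YGR183C) of complex III at 893 in WT and 1451 to 2433. Of 17 genes of the TCA cycle, 8, 8, 7 and 12 were at least 1.5-fold higher and 1, 0, 1 and 0 lower, with medians of 0.58, 0.52, 0.54 and 0.74 and percentile 100 in each. CIT1 (YNR001C), the mitochondrial citrate synthase, lay at 65.1 FPKM in WT and 165 to 189 in the mutants. Mitochondrial ribosomal proteins lay closer to WT. Of 61, 0, 0, 1 and 2 were 1.5-fold higher and 1 in each mutant lower, with medians of 0.02, 0.04, 0.05 and 0.18 and percentiles of 94.2, 98.5, 94.3 and 99.8. With random lists matched on length these were 76.7, 87.3, 75.9 and 92.2. In ies6d 49 of the 61 lay above WT. MRPL8 (YJL063C) was the 1 lower in all 4, at 175 FPKM in WT and 78.0 to 101 in the mutants. For the respiratory and TCA cycle lists the percentiles matched on length were 100.

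Genes of glucose use were split. Of 17 glycolysis genes, 10 were at least 1.5-fold lower in ino80d, 2 in arp8d, 8 in arp5d and 4 in ies6d, and 3, 5, 4 and 4 were higher. The medians were -0.76, -0.23, -0.56 and -0.29, at percentiles of 0.20, 64.6, 0.18 and 8.44, while the means were -0.30, 0.23, -0.09 and 0.21, of the opposite sign in arp8d and ies6d. Against random lists without ribosomal protein genes the percentiles were 0.040, 20.9, 0.025 and 2.64, and against lists matched on length 0.29, 81.3, 0.36 and 33.1. The 3 higher in all 4 were CDC19, HXK1 (YFR053C), the hexokinase of poor carbon sources, at 29.5 FPKM in WT and 206, 281, 310 and 503 FPKM in the mutants, and GLK1 (YCL040W), glucokinase, at 93.0 in WT and 194, 328, 313 and 531 in the mutants. GLK1 lies on chromosome III and overlaps YCL042W. TDH2 (YJR009C), with the near-identical copies TDH1 and TDH3, lay at 7909 FPKM in WT and at 2839, 5191, 3607 and 3851 FPKM in the mutants. Of 8 genes of ethanol fermentation, 3, 2, 2 and 1 were at least 1.5-fold higher and 3, 1, 4 and 3 lower, with medians of -0.19, -0.19, -0.35 and -0.31 and means of 0.21, 0.30, 0.08 and 0.00. With members of at least 20 FPKM alone the median was -0.69 in ino80d, -0.68 in arp5d and -0.61 in ies6d. PDC1 (YLR044C), the main pyruvate decarboxylase, lay at 6625 FPKM in WT and 3528 to 4873 in the mutants, and PDC6 (YGR087C), a minor one, at 0.719 and 5.53 to 15.6.

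Genes that glucose represses were higher in part. Of 14 kept genes, 7, 6, 7 and 8 were at least 1.5-fold higher, 3 of them in all 4 mutants, and none was 1.5-fold lower. Above WT by any amount were 10, 11, 10 and 10. The medians were 0.65, 0.49, 0.60 and 0.68, at percentiles of 99.2 to 99.9. GAL7 (YBR018C) lay at 4.15 FPKM in WT and 10.4 to 14.4 in the mutants, and CYB2 (YML054C), L-lactate cytochrome c oxidoreductase, at 12.5 and 32.1 to 37.2. GAL1 (YBR020W) and GAL10 (YBR019C) went the other way. GAL1 lay at 8.01 FPKM in WT and 5.82 to 6.71 in the mutants, and GAL10 at 9.78 and 6.65 to 7.24. Both overlap YNCB0008W. Of 10 hexose transporter genes, 2, 4, 2 and 2 were at least 1.5-fold higher and 1, 0, 1 and 0 lower, with medians of 0.04, 0.47, 0.16 and 0.15. The median of arp8d was 1.08 with members of at least 20 FPKM and that of ies6d 0.49 with no filter. HXT7 lay at 2.71 FPKM in WT and 27.9 to 57.6 in the mutants, and HXT4 (YHR092C) at 42.2 and 79.9 to 173. HXT1 (YHR094C), the low-affinity transporter, was higher in arp8d, at 569 FPKM against 257 in WT, and lay at 133 in ino80d, 161 in arp5d and 230 in ies6d. HXT1 was named after its values were seen. Of 17 genes of fatty acid oxidation, 4, 3, 5 and 4 were at least 1.5-fold higher and 0, 1, 1 and 0 lower, with medians of 0.17, 0.27, 0.28 and 0.31. Their percentiles were 45.4, 85.7, 82.0 and 91.25, less extreme than those of the glucose-repressed genes. CAT2 (YML042W), carnitine acetyltransferase, lay at 7.86 FPKM in WT and at 8.93, 16.7, 17.0 and 17.8 FPKM in the mutants.

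Cytosolic ribosomal protein genes were lower, most in ino80d. Of 135 genes, at least 1.5-fold lower were 101 in ino80d, 62 in arp8d, 46 in arp5d and 23 in ies6d, and the 23 were lower in all 4. None was 1.5-fold higher. The medians were -0.73, -0.56, -0.49 and -0.31, at percentile 0 in each mutant. RPS8A (YBL072C, near-identical copy RPS8B) lay at 2340 FPKM in WT and at 285, 518, 570 and 688 FPKM in the mutants, and RPL7B (YPL198W), which holds SNR59 in an intron, at 465 in WT and 80.3, 150, 89.0 and 108. Ribosome biogenesis factors moved less: of 107, 1, 0, 2 and 1 were 1.5-fold lower and none higher, with medians of -0.17, -0.13, -0.10 and -0.11 and percentiles of 7.08, 11.6, 21.9 and 12.8. With random lists matched on length these were 38.9, 61.8, 66.7 and 88.4. RRP1 (YDR087C) lay at 258 FPKM in WT and 161 to 215 in the mutants. None of the 19 genes of RNA polymerases I and III was 1.5-fold away, with medians of -0.14, -0.07, -0.12 and -0.18.

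Most late G1 genes lay below WT, and fewer passed 1.5-fold. Of 17 G1/S genes, 9, 7, 8 and 7 were at least 1.5-fold lower, 4 of them in all 4 mutants, and none was 1.5-fold higher. Above WT by any amount were 2, 2, 3 and 3. The medians were -0.68, -0.34, -0.53 and -0.57, at percentiles of 0, 0.13, 0 and 0. CLN1 (YMR199W), a G1 cyclin, lay at 117 FPKM in WT and 35.8 to 43.9 in the mutants, CLB6 (YGR109C) at 16.6 and 4.94 to 7.48, and SVS1 (YPL163C) at 343 and 164 to 217. Of 16 G2/M genes, 1, 4, 3 and 4 were at least 1.5-fold lower and none higher, with medians of 0.14, -0.20, -0.03 and -0.20. CLB1 (YGR108W), the member lower in all 4, lay at 93.0 FPKM in WT and 30.0 to 40.8 in the mutants. Of 15 M/G1 and daughter cell genes, 2, 1, 3 and 3 were higher and 1, 0, 0 and 0 lower, with medians of 0.08, 0.11, 0.28 and 0.31. PIR3 (YKL163W) lay at 12.7 FPKM in WT and 21.2 to 29.3 in the mutants. The cultures were asynchronous.

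Of 28 DNA replication genes, 1, 1, 4 and 2 were at least 1.5-fold lower and none higher, with medians of -0.13, -0.25, -0.26 and -0.28 and percentiles of 5.60, 0.13, 0.51 and 0.35. CDC9 (YDL164C), DNA ligase, lay at 38.9 FPKM in WT and 24.6 to 25.8 in the mutants. Of 12 DNA damage response genes, 5, 4, 5 and 5 were at least 1.5-fold lower, 4 of them in all 4 mutants, and 1, 0, 0 and 1 higher, with medians of -0.36, -0.39, -0.36 and -0.45 and percentiles of 0.71, 0.10, 0.66 and 0.32. With members of at least 20 FPKM the medians were -0.67, -0.62, -0.66 and -0.63. HUG1 lay at 983 FPKM in WT and 76.2 to 164 in the mutants. RNR4 (YGR180C) and RNR2 (YJL026W), subunits of ribonucleotide reductase, lay at 834 and 306 FPKM in WT, and at 280 to 372 and 165 to 198 in the mutants. Of 10 histone genes, 2, 0, 1 and 0 were 1.5-fold lower and none higher, with medians of -0.31, -0.27, -0.11 and 0.02. Their percentiles were 85.4, 75.7, 86.1 and 86.2, or 35.6, 23.9, 48.7 and 43.6 matched on length. The histone list was thus not low for features of like expression. HTA1 (YDR225W, near-identical copy HTA2) lay at 4052 FPKM in WT and at 2368, 2992, 3830 and 3677 FPKM in the mutants. Of 11 genes of the SWR1 complex and H2A.Z, 2, 0, 2 and 2 were 1.5-fold higher and none lower, with medians of 0.23, 0.04, 0.22 and 0.13, that of arp5d being 0.00 with members of at least 20 FPKM. YAF9 (YNL107W) lay at 64.5 FPKM in WT and 93.0 to 112 in the mutants.

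The medians of the phospholipid, ergosterol and iron lists lay below 0 in all 4 mutants. The INO80 complex carries its name from inositol, and INO1 (YJL153C), the inositol synthesis enzyme, lay at 6.61 FPKM in WT and at 8.68, 6.88, 8.54 and 7.80 FPKM in the mutants in this rich medium. Of 16 inositol-regulated genes of phospholipid synthesis, 6, 4, 4 and 5 were at least 1.5-fold lower, 3 of them in all 4, and none higher, with medians of -0.37, -0.38, -0.41 and -0.34 and percentiles of 0.34, 0.030, 0.090 and 0.25. CPT1 (YNL130C), cholinephosphotransferase, lay at 139 FPKM in WT and 69.5 to 87.9 in the mutants, and OPI3 (YJR073C) at 212 and 106 to 156. Of 23 ergosterol genes, 8, 2, 4 and 5 were at least 1.5-fold lower and 0, 0, 1 and 0 higher, with medians of -0.36, -0.21, -0.27 and -0.31 and percentiles of 1.35, 7.88, 1.27 and 0.41. With random lists matched on length these were 11.9, 30.5, 7.93 and 3.78. ERG1 (YGR175C), squalene epoxidase, lay at 544 FPKM in WT and 195 to 283 in the mutants. Of 18 genes of the iron regulon, 7, 3, 7 and 12 were at least 1.5-fold lower and 1, 2, 1 and 1 higher, with medians of -0.53, -0.27, -0.46 and -0.70 and percentiles of 0.040, 1.24, 0.010 and 0. ARN2 (YHL047C), a siderophore transporter, lay at 148 FPKM in WT and at 49.8, 102, 57.1 and 45.0 FPKM in the mutants, and HMX1 went the other way, from 12.8 FPKM in WT to 170 to 216.

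Of 12 hypoxic and anaerobic genes, 6, 4, 6 and 6 were at least 1.5-fold lower and 1, 3, 1 and 2 higher, with medians of -0.39, -0.19, -0.38 and -0.44. TIR1 lay at 240 FPKM in WT and at 9.78, 30.5, 12.2 and 10.8 FPKM in the mutants, and TIR3 (YIL011W) at 92.9 and 21.7 to 29.4, while TIR2 (YOR010C) lay at 33.8 in WT and 60.1 to 76.9. Of 9 kept genes of the seripauperin (PAU) family, most with near-identical copies, 3, 1, 1 and 1 were higher and 2, 2, 4 and 2 lower, with medians of -0.19, -0.16, -0.27 and -0.15. Without genes of chromosomes I, III and XI they were -0.41 in arp8d and -0.59 in arp5d. PAU5 (YFL020C), which has no such copy, lay at 48.1 FPKM in WT and 10.7 to 18.1 in the mutants. The COS family was lowest in ino80d. Of 8 genes matched by name alone, 6, 2, 4 and 3 were at least 1.5-fold lower and none higher, with medians of -2.02, -0.14, -0.57 and -0.46. That of arp8d was -0.63 with members of at least 20 FPKM. The name match took in COS111 (YBR203W, chromosome II, 629168 to 631942), and its place in the family was not checked. COS111 has no near-identical copy, and its log2 ratios were -0.28, -0.02, -0.25 and -0.11. Medians without COS111 were not computed. COS10 (YNR075W) lay at 25.3 FPKM in WT and at 4.84, 22.7, 14.4 and 10.8 FPKM in the mutants. COS7 (YDL248W), with the near-identical copy COS5, lay at 19.2 FPKM in WT and at 2.66, 14.9, 11.6 and 10.5 FPKM.

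Most genes of the mating pathway stayed within 1.5-fold of WT. Of 19 a-cell and pheromone genes, 2, 2, 3 and 5 were at least 1.5-fold higher and 2, 5, 3 and 2 lower, with medians of -0.01, -0.09, 0.01 and 0.20. That of arp5d was -0.14 among long ORFs. FUS3 (YBL016W), the kinase of the pheromone pathway, lay at 133 FPKM in WT and at 34.0, 56.9, 25.3 and 31.5 FPKM in the mutants, and FUS1 (YCL027W) at 22.3 and 45.1 to 64.2. MFA1 (YDR461W), the a-factor gene, lay at 203133 FPKM in WT, 600141 in ino80d, 194434 in arp8d, 476819 in arp5d and 635234 in ies6d. Its ORF is shorter than most. Of 4 alpha-cell genes, 3, 2, 3 and 3 were at least 1.5-fold higher, with medians of 1.09, 0.65, 1.14 and 1.16. That of arp8d was 0.28 with members of at least 20 FPKM. MF(ALPHA)1, the alpha-factor gene, lay at 1.69 FPKM in WT and at 34.5, 19.8, 41.5 and 37.8 FPKM in the mutants. Of 28 kept genes of meiosis and sporulation, 14, 12, 14 and 13 were at least 1.5-fold higher and 1 in each mutant lower, with medians of 0.52, 0.39, 0.54 and 0.48 and percentiles of 95.5 to 99.3, or 93.2 to 99.2 matched on length. With a pseudocount of 5 FPKM the median was 0.25 in arp8d and 0.34 in arp5d. SPR3 (YGR059W), a sporulation septin, lay at 1.25 FPKM in WT and 7.02 to 10.6 in the mutants, and REC8 (YPR007C), the meiotic cohesin subunit, at 1.28 and 6.09 to 7.68.

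Values of features listed as small nucleolar RNAs were higher in the mutants. The libraries were made from poly(A) RNA, and how far these values measure the RNAs themselves was not tested. Of 51, 35, 25, 35 and 28 were at least 1.5-fold higher and 6, 5, 5 and 5 lower, with medians of 0.83, 0.51, 1.03 and 0.73 and percentile 100 in each. Their IDs carry no length in the annotation, so that a check for length was void. Of 53 kept features with such an ID, 9 were listed at 0 in 1 strain or more. One of them, snR64, lay at 3420 FPKM in WT, 2762 in arp8d and 0 in the other 3 strains. Besides glycolysis and ethanol fermentation, a list's median and mean differed in sign for the marker genes in arp5d, at -0.02 and 2.14, for INO80 subunits in ies6d, at 0.03 and -0.40, and for the PAU family in ino80d, at -0.19 and 0.17. They also did for the a-cell genes in arp5d, at 0.01 and -0.07, for mitochondrial ribosomal proteins in arp8d, at 0.04 and -0.02, and for the proteasome in ies6d, at -0.01 and 0.01.

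**Figure D2:**
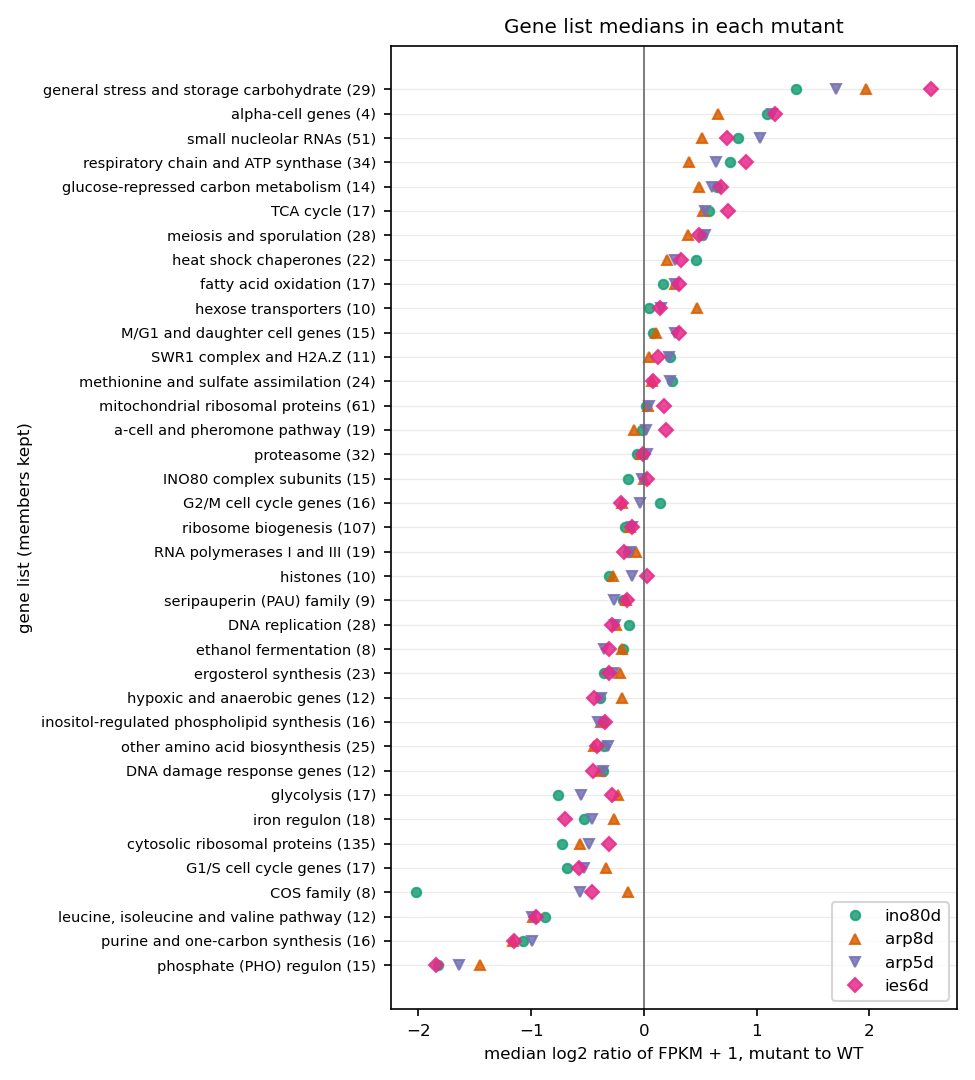
Median log2 ratio of FPKM + 1 to WT (horizontal axis) of each gene list with its kept members in parentheses (vertical axis), 1 point per mutant, without the marker genes. The general stress list lay highest, from 1.35 in ino80d to 2.55 in ies6d, and the phosphate list between -1.84 in ies6d and -1.45 in arp8d, while the COS list lay at -2.02 in ino80d alone.

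The mutants were closer to each other than to WT. The SD of the log2 ratio over 6192 features was 0.776 to 0.883 between WT and a mutant, and 0.504 to 0.582 between mutants. Over long ORFs it was 0.592 to 0.678 against WT and 0.248 to 0.349 between mutants. By this measure arp5d and ies6d were the closest pair of long ORF profiles, at 0.248, with 15 of 5419 ORFs 2-fold apart, and ino80d and arp5d the next at 0.278 with 16. Over all kept features ino80d and arp5d were closest, at 0.504. WT and arp8d were the closest pair that held WT.

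Setting arp5d and ies6d against arp8d and ino80d asks whether mutants of the subunits Arp5 and Ies6 differ together from the other two. Few genes set them apart. YBR072C-A, YCR038W-A, RRT15 and YNR001W-A were at least 2-fold higher in each of the 4 cross pairs, and MET17 and YMR230W-A were lower, 4 and 2 features of 6192. MET17 was the only long ORF, and it stood near its WT value in arp5d and ies6d and far above it in arp8d and ino80d. With no filter on low values the 6 became 11, and with a mean of at least 20 FPKM they became 2. The other ways to pair the mutants gave similar counts: 4 higher and 4 lower for arp5d and ino80d, with LYS2 and IMD2 among the lower, and 5 higher and 3 lower for arp5d and arp8d, none of them a long ORF. Of the 10 highest features in this comparison, 9 were listed at 0 in 1 strain or more. URA1 (YKL216W), dihydroorotate dehydrogenase, was among the highest long ORFs, at 1661 FPKM in WT, 1503 in arp5d and 1690 in ies6d, against 791 in arp8d and 820 in ino80d.

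Some whole chromosomes lay apart from the other mutants, over annotated genes above 0 in all 5 strains. In ino80d the 84 genes of chromosome I had a median log2 ratio of 0.69 to WT, 1.62-fold, and 0.55 to the mean of the other 3 mutants, with 83 of the 84 above it. In the other mutants chromosome I lay at 0.08 to 0.13 against WT. CDC19 (YAL038W), pyruvate kinase, is on this chromosome but lay at 1024 FPKM in WT and at 2120, 2347, 1760 and 1969 FPKM in the mutants. In ies6d the 156 genes of chromosome III had a median of 0.36 to WT and 0.24 to the mean of the other mutants, with 141 above it. The 306 genes of chromosome XI had 0.11 and 0.11, with 241 above. In arp5d the 266 genes of chromosome V had -0.02 to WT and 0.08 to the mean of the other mutants, with 190 above. Medians of stretches along this chromosome ran from -0.13 to 0.14. Near chromosome ends, within 20 kb, more genes were changed in all 4 mutants, in both directions. Of 140 such genes, 15% were at least 2-fold lower in ino80d, 7.14% in arp8d, 8.57% in arp5d and 7.86% in ies6d, against 3.77%, 2.04%, 3.12% and 2.97% of 5484 genes elsewhere. At least 2-fold higher were 12.9%, 11.4%, 18.6% and 15%, against 5.67%, 4.38%, 5.03% and 6.27%. These sets were not matched on expression, and genes with near-identical copies stayed in, so position cannot be told apart from either.

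**Figure D3:**
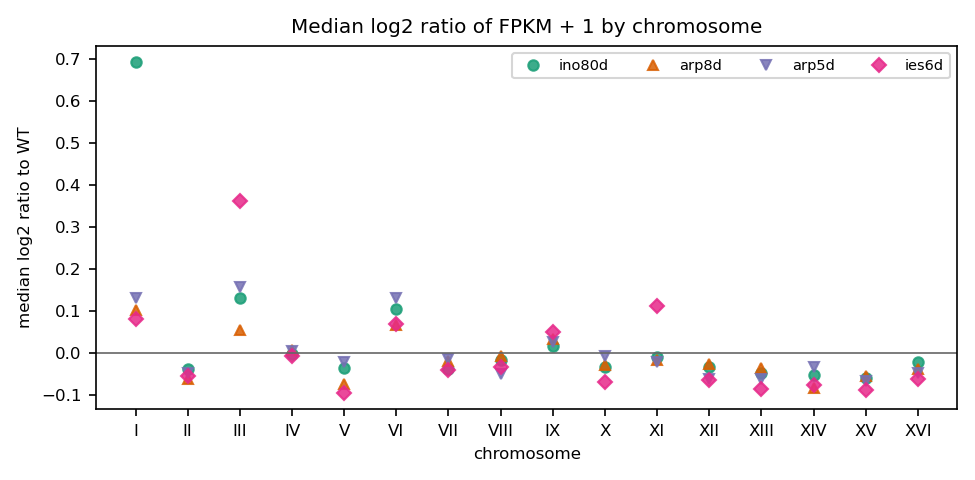
Median log2 ratio of FPKM + 1 to WT (vertical axis) over the kept genes of each chromosome (horizontal axis), 1 point per mutant. Chromosome I lay at 0.69 in ino80d and at 0.08 to 0.13 in the other mutants, and chromosome III at 0.36 in ies6d.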

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

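The search for genes that moved in opposite directions was limited to annotated ORFs of at least 300 bp above 0 in all 5 strains, and widened to members of the gene lists, only after the values were seen. Before that it had given 8 features, nearly all of them short, unmatched or listed at 0 in some strain (DGR1, YBR103C-A, YDR524C-A, YIR018C-A, YKL106C-A, snR18, snR48 and YGL149W). With both changes 2 genes were found, of which YGL149W was among the 8 and HXT1 came in through the lists. The differences were not tested, because each strain has 1 value, and no technical or biological explanation was tested for either gene.

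YGL149W was at least 1.5-fold higher than WT in ino80d and at least 1.5-fold lower in the other 3 mutants. Its log2 ratio to WT was 2.26 in ino80d, -1.43 in arp8d, -0.95 in arp5d and -2.78 in ies6d, and the ratio in ino80d exceeded that in ies6d by 5.04. The gene lies next to INO80, which LEU2 replaced in ino80d, and the libraries do not record the strand.

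HXT1 was higher than WT in arp8d and lower in ino80d and arp5d. Its log2 ratio to WT was -0.95 in ino80d, 1.14 in arp8d, -0.68 in arp5d and -0.16 in ies6d, and the ratio in arp8d exceeded that in ino80d by 2.09.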

How the results depend on the processing

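The alternatives on features (above 0 in all 5 strains, long ORFs) and on chromosomes (without I, III and XI), and the sizes that count as a move, were chosen after the data were seen. No list past its threshold turned to the opposite direction under any alternative run. A gene past 2-fold could not turn. A pseudocount keeps the sign of its ratio, filters leave the ratio unchanged, and the centring shifts were far smaller. Some medians near 0 changed sign, such as those of methionine genes in ies6d and a-cell genes in arp5d. A count or a distance counts as moved beyond 1.5 times, a list median beyond the SD of its random lists, and a gene beyond 0.379 on the log2 scale. Of the values recomputed, 84 counts stayed and 12 moved, 1156 list medians stayed and 44 moved, and 60 distances stayed and 20 moved. Of the ratios of named genes, 6908 stayed and 328 moved, all of these with another pseudocount. Filters and feature sets leave a gene's ratio as it is and the centring shifts were small, so only a pseudocount could move a gene. With 0.1 FPKM 854 ratios stayed and 118 moved, and with 5 FPKM 762 stayed and 210 moved. The cause of each move was not tested, except that a lower fold threshold passes more genes and a stricter filter leaves fewer. Centring each strain on its median moved no value beyond these sizes, with shifts of -0.014, -0.021, -0.022 and -0.024. No paired analysis was possible because each strain has 1 value for both replicates, and for the same reason the planned runs without a replicate and with a replicate block were not run. The depth is unknown, so what it limits could not be computed.

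At a 1.5-fold threshold, features higher and lower numbered 935 and 819 in ino80d, 680 and 516 in arp8d, 825 and 677 in arp5d, and 890 and 641 in ies6d. Features 2-fold apart between arp5d with ies6d and arp8d with ino80d numbered 11 with no filter, 2 with a mean of at least 20 FPKM, 3 among features above 0 in all strains and 1 among long ORFs.

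With a pseudocount of 0.1 FPKM the median of the marker genes was 9.14 in ino80d and 9.59 in arp8d. With 5 FPKM it was 4.25 and 4.68, and the general stress median was 1.16 in ino80d, 1.73 in arp8d, 1.58 in arp5d and 2.29 in ies6d. With 5 FPKM the meiosis median was 0.36 in ino80d, 0.25 in arp8d and 0.34 in arp5d, the COS median -1.54 in ino80d, and the glucose-repressed median 0.45 in ino80d and 0.47 in ies6d. With no filter the phosphate median was -1.58 and the PAU median -0.39 in arp8d, and the hexose transporter median 0.49 in ies6d.

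With a mean of at least 20 FPKM the median of SWR1 and H2A.Z was 0.00 in arp5d (-0.001), and that of ethanol fermentation -0.69 in ino80d, -0.68 in arp5d and -0.61 in ies6d. General stress stood at 1.53 in ino80d, 2.07 in arp8d and 1.81 in arp5d, alpha-cell genes at 0.28 in arp8d, and the COS family at -1.41 in ino80d and -0.63 in arp8d. Hexose transporters stood at 1.08 in arp8d, glucose-repressed genes at 0.78 in arp5d, and DNA damage response genes at -0.67, -0.62, -0.66 and -0.63 in ino80d, arp8d, arp5d and ies6d.

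Without genes of chromosomes I, III and XI the medians were -1.58 for phosphate genes in arp8d, -0.041 for methionine genes in ies6d and -1.16 for purine genes in arp5d. Heat shock chaperones stood at 0.32 in ino80d, 0.10 in arp8d and 0.14 in arp5d, alpha-cell genes at 0.28 in arp8d, and the PAU family at -0.41 in arp8d and -0.59 in arp5d. The a-cell median in arp5d was -0.14 there and -0.14 among long ORFs.

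As median absolute log2 ratio, distances from WT were 0.34 for ino80d, 0.26 for arp8d, 0.30 for arp5d and 0.31 for ies6d. Those of ino80d were 0.15 from arp8d, 0.13 from arp5d and 0.17 from ies6d, those of arp8d 0.13 from arp5d and 0.16 from ies6d, and that of arp5d 0.12 from ies6d. Among features above 0 in all strains the SD was 0.36 between ino80d and arp8d, 0.30 between ino80d and arp5d, 0.36 between arp8d and ies6d and 0.28 between arp5d and ies6d. Among long ORFs it was 0.33, 0.28 and 0.35 between ino80d and arp8d, arp5d and ies6d, 0.31 and 0.33 between arp8d and arp5d and ies6d, and 0.25 between arp5d and ies6d.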

Other observations

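Of the tests in this part, that of gene length on chromosome I was chosen before its result was seen, as was the first form of that on the neighbours of MET17 and LYS2, which was then replaced. All others, and the form that replaced it, were chosen after. The naming of genes by their place among long ORFs was also chosen after the data were seen.

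Genes outside the lists also lay apart from WT in the same direction in the mutants. FET4 (YMR319C), a low-affinity iron transporter, lay at 155 FPKM in WT and at 42.9, 59.4, 43.9 and 34.3 FPKM in ino80d, arp8d, arp5d and ies6d. ALD5 (YER073W), a mitochondrial aldehyde dehydrogenase, lay at 229 FPKM in WT and at 69.3, 37.2, 50.8 and 44.8 FPKM in the same order, and NMD5 (YJR132W), a nuclear import receptor, at 48.1 and 13.0, 12.8, 11.1 and 11.0. NQM1 (YGR043C), a transaldolase, lay at 8.39 FPKM in WT and at 48.8, 79.1, 48.6 and 74.9 FPKM.

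Nearly all genes of chromosome I were higher in ino80d. Scaling of the ino80d values was excluded, since genes off the chromosome lay at -0.007 against the other mutants, as was a single stretch, since the lowest of 8 stretches stood at 0.41. Gene length was excluded too, since the lowest of 3 length classes stood at 0.45. Extra copies of the chromosome in part or all of the cells may account for it, since 98.8% of its genes lay above the mean of the other 3 mutants. This is a hypothesis found and tested on the same data, and no DNA was measured.

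MET17 and LYS2 were near 0 in some strains and expressed in others. Libraries swapped between mutants were excluded, since all 4 deleted genes were low in their own strain and expressed in the other 4. A lost or silent region that took in the 9 genes tested within 5 kb was excluded, since the lowest difference over them was -0.32. Genes that overlap MET17 or LYS2, such as YLR302C, and features listed at 0 in a strain did not enter. A smaller loss around either gene was therefore not tested. The first bound for that test, on the largest absolute difference, was written before its result was seen and was exceeded by TKL2 at 1.17, which was higher in the strains with low LYS2; the measure was changed after that was seen to the lowest difference, which is the one a loss predicts. Different marker alleles may account for it, as a hypothesis, since the highest of the low values was 0.571 FPKM and that left of a deleted gene was 0.211 FPKM. MET17 is deleted in BY4741 but was expressed in ino80d and arp8d, which argues against that deletion in these mutants. For LYS2 the allele stays a hypothesis, and no DNA was measured.

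Many genes differed from WT the same way in all 4 mutants. Noise of equal size in every strain was excluded, since the smallest distance of a mutant from WT was 1.33 times the largest between mutants over all kept features, and 1.70 times over long ORFs. A WT culture or library that differs for other reasons cannot be told apart from the missing subunits, since there is 1 WT value per gene. The LEU2 marker cannot be told apart from them either, since each mutant carries it: the medians of the leucine, isoleucine and valine list spanned 0.11 over the mutants. The strains also differed in their MET17 and LYS2 values, and other allele differences between WT and the mutants were not examined. The missing subunits stay open as the biological explanation and were not tested apart from these.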
